A study of Mus musculus with 24 samples.

How the data were processed

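RNA from 24 subcutaneous plasmacytomas was profiled on an Affymetrix array of human gene probe sets. Per the labels' protocols, MM.1S cells, a human multiple myeloma line, were injected with Matrigel into immunodeficient CB17-SCID mice, and mice with palpable tumours were randomised to vehicle or to treatment. Total RNA was isolated with a miRNeasy kit and labelled with biotin, again per the labels' protocols. The labels name the mouse as the organism, whereas the probe table names human genes, so the values describe the human tumour cells and any mouse RNA that cross-hybridised. The 8 groups held 3 arrays each. They were control, the 3 single drugs, the 3 pairs of drugs and the triple combination. Doses in the labels were 10 mg/kg filanesib, 0.5 mg/kg dexamethasone and 8 mg/kg pomalidomide, for 2 days. The labels do not say explicitly that each array came from a separate animal, so p-values measure the spread between these samples.

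The deposited values were log2 expression levels per probe set, made by the authors with the RMA method (background correction, quantile normalisation and summary of probes) in Affymetrix Expression Console, per the submitters' processing notes. Software versions were not given in the sources used here. The value table held 53617 probe sets with no missing value, between 1.26 and 13.6 on the log2 scale. The medians of the 24 arrays lay between 3.65 and 3.73. Quantile normalisation makes the arrays alike in their overall distribution, so a change shared by most genes would not be visible. The probe table named 1 gene symbol for 16098 probe sets and none for 37519, which were left out of the tests by gene. For the 779 genes with more than 1 probe set, the probe set with the highest mean was used, which left 14884 genes. Of these, 11727 carried a protein-coding accession and 1088 were microRNA genes. Genomic positions were not used here.

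Levels were compared with limma 3.58.1 in R 4.3.3. A linear model with a mean per group was fitted to all 24 arrays, which left 16 residual degrees of freedom, and variances were moderated with eBayes. P-values were two-sided and adjusted by the Benjamini-Hochberg method within each comparison, with a threshold of 0.05. Each treatment was compared with control, and the triple combination with pomalidomide plus dexamethasone. For each drug an average effect was taken, the mean of its 4 differences with and without the drug over the backgrounds formed by the other 2 drugs, which sets 12 arrays against 12. The difference between the effect of filanesib beside pomalidomide and dexamethasone and its effect alone was tested directly. A corresponding pair of differences for pomalidomide, beside dexamethasone and beside filanesib, was added after the data had been seen. Changes are given as log2 differences with the standard error (SE) of the model, and group levels as mean ± SD. The number of arrays limits the precision: the median SE was 0.14 for a difference between 2 groups and 0.07 for an average effect. Simulated data used normal noise, alike in all arrays and independent between genes, with 100 genes changed by 0.5 and 100 by 1 on the log2 scale. There the comparison of filanesib with control recovered 35 and 94 of them, and the average effect 96 and 100. Of the 135 and 211 genes called, 6 and 15 were unchanged ones. The measured arrays differed in spread, so recovery in them may differ.

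Gene lists covering the cell cycle, cell death, hormone, interferon and stress responses, metabolism, plasma cell identity and markers of other cell types were tested with limma's fry, which asks whether the genes of a list move, on balance, in 1 direction. Lists with at least 5 measured members were tested, 24 in all, with adjustment over the lists. As an alternative, camera compared each list with all other genes using an estimated correlation between its genes. Counts of changed members are given over all genes tested and adjusted over the list alone. Comparisons, lists, tests and most alternatives were fixed before the data were examined. The rule for naming genes, fixed at the same time, took the largest rises and falls past the threshold (for pairs of groups, only genes whose groups did not overlap), up to 4 members of each list with the smallest p, and a short series of genes of interest, among them KIF11, CCNB1, BCL2L11, MCL1, IRF4, MYC, IKZF1, IKZF3, CRBN and FKBP5. HRK, TSC22D3 and CDKN1A were in that series but were not named by the probe table.

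Alternatives comprised a further quantile normalisation, centring of each array on its median, omission of dim genes, array weights, a trended and robust variance prior, the replicate number as a block, a minimum change of 1.5-fold, a test of every probe set, a fit restricted to the compared groups, and omission of each array in turn. A test of protein-coding genes only, removal of replicates 1 and 3 of pomalidomide alone, and omission of arrays outside the compared groups, were added after the data had been seen. For average effects and differences of effects, a fit to the compared groups only was run where the comparison did not already use all groups.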

Results

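Expression was measured in MM.1S plasmacytomas, tumours of a human multiple myeloma line grown under the skin of mice, after 2 days of treatment. Filanesib inhibits the kinesin spindle protein KIF11 (also called Eg5 or KSP), a motor that separates the spindle poles in mitosis. Pomalidomide binds cereblon and directs the lymphoid transcription factors IKZF1 and IKZF3 to degradation, and dexamethasone is a glucocorticoid. Each drug was present in 4 groups and absent from 4, with 3 arrays per group and 24 in all, so that every combination of the 3 drugs was represented. Correlations between arrays across probe sets lay between 0.962 and 0.994. The 3 arrays of pomalidomide alone differed most from each other: their residual SD was 0.232, 0.193 and 0.288, against 0.127 to 0.180 in the other 21 arrays.

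Genes of mitosis and the spindle rose with filanesib in its average effect over backgrounds. The strongest evidence was for CDC20, the activator of the anaphase-promoting complex (probe set 16663514), which rose by 0.71 ± 0.06 on the log2 scale (SE, 12 arrays against 12, 1.64-fold, limma adjusted p = 1.44e-06). The checkpoint kinase BUB1 (probe set 16901755) rose by 0.63 ± 0.07 (adjusted p = 1.01e-05), the mitotic kinase PLK1 by 0.63 ± 0.07 (adjusted p = 3.98e-05) and cyclin B1, CCNB1, by 0.61 ± 0.10 (adjusted p = 0.0017). The drug's own target KIF11 rose by 0.49 ± 0.10 (adjusted p = 0.0078), and the related motor KIF15, which can also separate spindle poles, by 0.36 ± 0.09 (adjusted p = 0.0374). Of 32 measured genes of the mitosis list, 31 rose over all genes tested and 32 adjusted over the list alone, with a median change of 0.50 (fry adjusted p = 1.23e-05, and 0.0031 with an estimated correlation). The list's median change with filanesib was 0.31 with no other drug, 0.58 beside dexamethasone, 0.52 beside pomalidomide and 0.62 beside both. Of these the first did not pass singly (fry adjusted p = 0.3031), the last did, and the 2 between were not tested as lists.

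The largest individual rises included the microRNA gene MIR4441 (0.82 ± 0.15), ARHGAP11A (0.78 ± 0.11) and its paralogue ARHGAP11B (0.79 ± 0.15), whose probes can share sequence, the cytokinesis motor KIF14 (0.72 ± 0.13) and the cyclin-dependent kinase subunit CKS2 (0.70 ± 0.11). DEPDC1 rose by 0.70 ± 0.10, the spindle-associated hyaluronan receptor HMMR by 0.67 ± 0.10, the Holliday junction resolvase GEN1 by 0.67 ± 0.13 and the mitotic kinase PBK by 0.65 ± 0.10. The centromeric histone CENPA rose by 0.48 ± 0.06, and survivin, BIRC5, which serves both in the chromosomal passenger complex and among inhibitors of apoptosis, by 0.46 ± 0.10. Of 27 measured DNA replication and G1/S genes, 3 rose over all genes, the replicative helicase component GINS1 (0.50 ± 0.07), the origin licensing factor CDC6 (0.43 ± 0.09) and MCM10 (0.29 ± 0.07). Adjusted over the list alone, 13 rose, and the list passed with a median of 0.18 (fry adjusted p = 0.0205, adjusted p = 0.1885 with an estimated correlation). Genes of ribosome production and MYC targets had a median change of 0.16 with 1 of 17 risen, LYAR (0.49 ± 0.12), and 9 adjusted over the list alone (fry adjusted p = 0.0341, adjusted p = 0.1968 with an estimated correlation).

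Falls with filanesib were fewer. INSIG1, which retains the sterol sensor in the endoplasmic reticulum, fell by 0.41 ± 0.08 (adjusted p = 0.0037). Beside dexamethasone its arrays overlapped, at 8.95 to 9.28 with filanesib and 8.77 to 9.38 without. LARGE2, a glycosyltransferase of dystroglycan, fell by 0.50 ± 0.08, the kinase DYRK1B by 0.50 ± 0.10, the ribonuclease ZC3H12A by 0.35 ± 0.07 and the hypoxia-inducible peptide adrenomedullin, ADM, by 0.34 ± 0.08. The sterol demethylation enzyme MSMO1 changed by -0.32 ± 0.08, which did not pass (adjusted p = 0.0621) and was not lower beside dexamethasone (0.11), and the list of cholesterol and fatty acid synthesis as a whole did not either (fry adjusted p = 0.1152), with 1 of 21 fallen over all genes and 5 adjusted over the list alone. None of 13 measured pro-apoptotic BCL2 family genes changed (fry adjusted p = 0.5154). BCL2L11, which encodes BIM, changed by 0.06 ± 0.11, PMAIP1, which encodes NOXA, by 0.17 ± 0.09, and the anti-apoptotic MCL1 by -0.06 ± 0.06. These averages mixed directions. BCL2L11 was lower with filanesib where pomalidomide was absent (-0.23 with no other drug, -0.28 beside dexamethasone) and higher where it was present (0.44, and 0.33 beside both). PMAIP1 was lower only with no other drug (-0.16), and MCL1 higher only beside pomalidomide (0.08). Genes listed as markers of other cell types moved slightly with filanesib. Human probes register mouse cells only by cross-hybridisation, so these values do not show a change in such cells. Endothelial markers had a median change of -0.05 with 0 of 10 passing (fry adjusted p = 0.0483, adjusted p = 0.1968 with an estimated correlation; PECAM1 -0.28 ± 0.09, but 0.18 with no other drug). Adipocyte markers had a median of -0.09 with 1 of 7 fallen, or 3 adjusted over the list alone, among them the triglyceride lipase PNPLA2, which was not lower where pomalidomide was the only other drug (0.11) (fry adjusted p = 0.0483, adjusted p = 0.2099 with an estimated correlation). The pericyte marker RGS5 rose by 0.27 ± 0.06, the 1 of 7 measured smooth muscle and pericyte markers to pass. That list had a median of -0.01 and did not pass (fry adjusted p = 0.3568).

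In total limma called 208 of 14884 genes for the average effect of filanesib, 186 higher and 22 lower. The count was 132 without filanesib replicate 1, 132 without filanesib replicate 3, 130 without replicate 1 of filanesib plus dexamethasone, 318 without pomalidomide replicate 1 and 330 with array weights. A further quantile normalisation gave 153 higher and 43 lower, a test of every probe set 128 in all, and 20 genes changed by at least 1.5-fold.

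**Figure D1:**
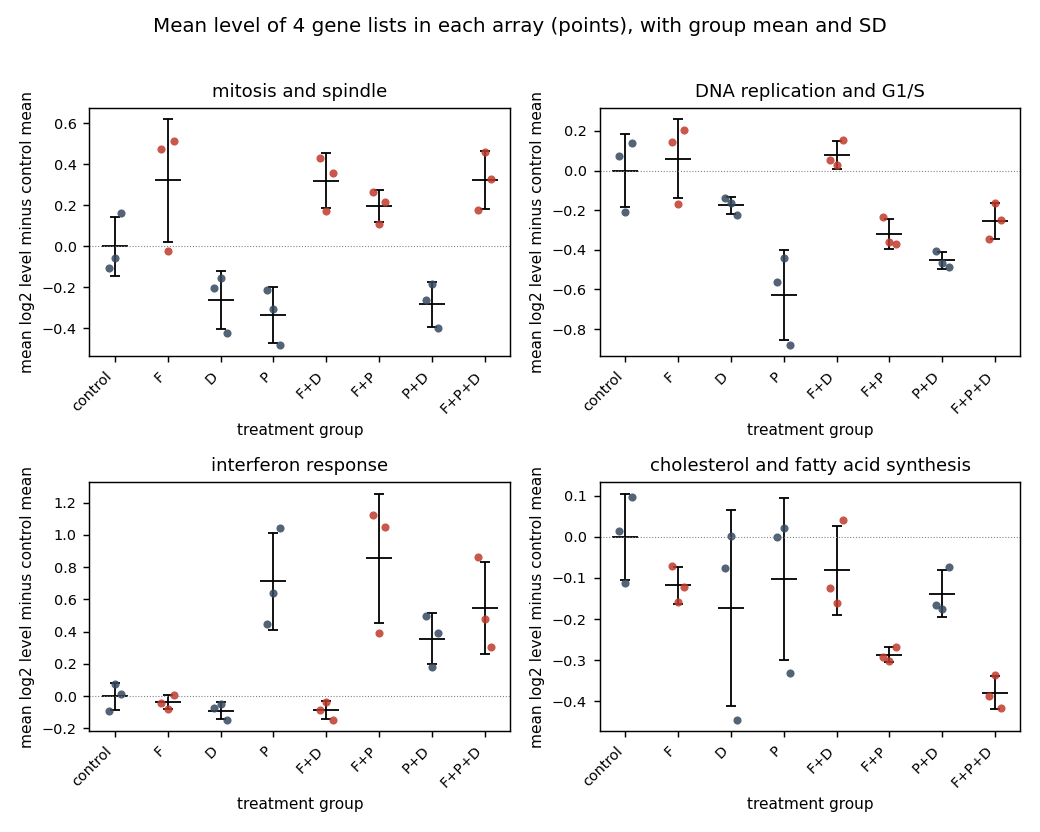
Mean log2 level of 4 gene lists in each array, relative to the control mean, by treatment group (F filanesib, D dexamethasone, P pomalidomide; red points with filanesib, dark points without; horizontal bars are group means and vertical bars SD, 3 arrays per group). The mitosis list lay at 0.32 ± 0.14 in the triple combination and at -0.28 ± 0.11 in pomalidomide plus dexamethasone, and the interferon list at 0.71 ± 0.30 in pomalidomide alone.

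The series asked what filanesib adds to pomalidomide and dexamethasone, which the triple combination against that pair addresses. Mitotic genes were again higher with filanesib: BUB1 rose from 7.78 ± 0.14 to 8.58 ± 0.09 (SD, 3 arrays each), a difference of 0.80 ± 0.13 (1.74-fold, limma adjusted p = 0.0423), and was the 1 gene past the threshold. CDC20 was at 7.49 ± 0.15 and 8.20 ± 0.04, a difference of 0.71 ± 0.13 that did not pass (adjusted p = 0.0645). The centrosomal kinase NEK2 (0.91 ± 0.19), the checkpoint protein MAD2L1 (0.75 ± 0.14), GINS1 (0.70 ± 0.14), CCNB1 (0.70 ± 0.21) and KIF11 (0.63 ± 0.20) were also higher without passing, with adjusted p from 0.0704 to 0.3245. Of the 32 mitotic genes, 32 had a positive difference, 1 passed over all genes and 29 adjusted over the list alone, with a median of 0.62 (fry adjusted p = 0.0054, and 0.0194 with an estimated correlation).

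The list of endoplasmic reticulum chaperones and unfolded protein response genes was lower in the triple combination, with a median of -0.18 and 0 of 11 passing singly (fry adjusted p = 0.0139, adjusted p = 0.1386 with an estimated correlation). Among them HYOU1 differed by -0.31 ± 0.12 and calreticulin, CALR, by -0.25 ± 0.10. That call was also lost without replicate 3 of either group (adjusted p = 0.093 and 0.0908). Among cholesterol and fatty acid genes the values were -0.60 ± 0.15 for INSIG1, -0.75 ± 0.19 for the fatty acid desaturase SCD and -0.59 ± 0.17 for MSMO1. None of 21 passed over all genes, 8 were lower adjusted over the list alone, and the list did not pass (fry adjusted p = 0.1014). Differences were 0.33 ± 0.21 for BCL2L11, -0.03 ± 0.12 for MCL1, -0.13 ± 0.23 for the plasma cell factor IRF4 and -0.08 ± 0.13 for MYC, none of which passed. The last 3 changed sign in omissions of 1 array.

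For the triple combination against the pair, 1085 of 14884 genes had an unadjusted p under 0.05, where chance gives a share of 0.05. The 2 groups did not overlap in 15.8% of genes, where chance gives 10% for 3 arrays against 3. The single call of BUB1 was lost without each of the 6 arrays, and 16 of all 24 omissions of an array left 0 genes, whereas omission of filanesib replicate 2 gave 17. The call was also lost after median centring and with a replicate block, and array weights gave 82 genes and removal of pomalidomide replicates 1 and 3 gave 17. Filanesib beside the pair was not shown to act differently from filanesib alone: the median difference between the effects on mitotic genes was 0.31 (fry adjusted p = 0.7311). The only gene past the threshold for that difference was the small Cajal body RNA SCARNA12. No call was left, with 0 genes, after a further quantile normalisation, with a replicate block, or in a fit to the compared groups only. Omissions of 1 array that left 0 genes included control replicates 1 and 3, filanesib replicates 2 and 3, and replicates 1 and 2 of pomalidomide plus dexamethasone.

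Pomalidomide raised genes of the interferon response, which cells express after interferon or nucleic acid sensing. XAF1, an interferon-induced antagonist of the inhibitor of apoptosis XIAP (probe set 16830202), rose by 1.57 ± 0.12 on average over backgrounds (12 arrays against 12, 2.97-fold, limma adjusted p = 3.14e-08). The chemokine CXCL10 rose by 1.94 ± 0.23 (3.83-fold, adjusted p = 1.75e-05), and the interferon-induced IFI44 by 1.44 ± 0.13 (adjusted p = 4.13e-07). IFI44L rose by 1.5 ± 0.18, the viral RNA binding protein IFIT1 by 1.28 ± 0.22 and its partner IFIT3 by 1.28 ± 0.23. The guanylate-binding protein GBP4 and the membrane protein IFITM1 each rose by 1.28 ± 0.17 and the GTPase MX2 by 1.26 ± 0.15. Of 30 measured interferon genes, 24 rose over all genes and 28 adjusted over the list alone, with a median of 0.53 (fry adjusted p = 1.27e-05, and 0.0066 with an estimated correlation). The immunoglobulin-like receptor MILR1 rose by 1.76 ± 0.20, and CD68, a lysosomal membrane protein used as a macrophage marker, by 0.99 ± 0.09 (1.99-fold, adjusted p = 4.31e-07). CD68 was the 1 gene of 12 measured macrophage markers to change, the median of the list was 0.01, and the list did not pass (fry adjusted p = 0.0533). The lysosomal protease CTSS, also abundant in macrophages, changed by 0.11 ± 0.07 (0.30 with pomalidomide alone and -0.05 beside filanesib).

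Genes of DNA replication and entry into S phase fell with pomalidomide. MCM10, which activates the replicative helicase, fell by 0.52 ± 0.07 (adjusted p = 1.09e-04), its partner CDC45 by 0.50 ± 0.07, thymidylate synthase, TYMS, by 0.49 ± 0.08 and the maintenance methylation factor UHRF1 by 0.35 ± 0.05. Of 27 measured replication genes, 25 fell over all genes and 27 adjusted over the list alone, with a median of -0.41 (fry adjusted p = 1.54e-05, and 0.0091 with an estimated correlation). Among 32 mitotic genes 4 fell (6 adjusted over the list alone), MAD2L1 by 0.39 ± 0.07, BIRC5 by 0.37 ± 0.10, the cyclin CCNF by 0.33 ± 0.08 and NUSAP1 by 0.31 ± 0.07, and the list did not pass (fry adjusted p = 0.1778). The fall of CCNF lay mostly in tumours without other drugs (-0.81, against -0.09 to -0.25 in the other backgrounds), and NUSAP1 did not fall beside filanesib plus dexamethasone (0.02). CCNB1 changed by 0.03 ± 0.10 (adjusted p = 0.9437), a value that turned negative with array weights and without pomalidomide replicates 1 and 3, and was positive without filanesib (0.16, and 0.19 beside dexamethasone) and negative with it (-0.23, and -0.025 beside both).

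The largest falls with pomalidomide were in AMPD1, the muscle-type AMP deaminase, by 1.17 ± 0.15 (adjusted p = 3.98e-05), and MYB, a transcription factor of blood progenitors, by 0.81 ± 0.11 (adjusted p = 7.81e-05). CBLN2, a synaptic protein, fell by 0.69 ± 0.09, ADAM23 by 0.69 ± 0.10 and C12orf75 by 0.68 ± 0.08. IRF4, on which myeloma cells depend, fell by 0.54 ± 0.11 (adjusted p = 0.0056) and the lymphocyte receptor CD48 by 0.31 ± 0.07, although CD48 was not lower with pomalidomide alone (0.19). The plasma cell surface enzyme CD38 rose by 0.18 ± 0.05 and cereblon itself, CRBN, by 0.20 ± 0.06 (adjusted p = 0.0457). The rise of CRBN came mainly from tumours without other drugs (0.60), against -0.015 beside filanesib, 0.025 beside dexamethasone and 0.18 beside both. The call of CRBN was lost in 18 of 24 omissions of an array and under 4 other alternatives, with adjusted p from 0.055 to 0.1499 in those 4. Transcripts of the degraded factors did not pass: IKZF1 changed by 0.21 ± 0.07 (adjusted p = 0.0763), with -0.19 for pomalidomide alone and positive values in the other backgrounds, and IKZF3 had a value near 0 with an SE of 0.10, whose sign varied between omissions of an array (adjusted p = 0.9921). IKZF3 was at -0.52 with pomalidomide alone, against 0.08 beside filanesib, 0.11 beside dexamethasone and 0.31 beside both. MYC changed by -0.13 ± 0.06 (adjusted p = 0.2878), with -0.51 for pomalidomide alone and between -0.10 and 0.08 in the other backgrounds. The plasma cell list had 2 genes up and 2 down of 22 (4 up and 2 down adjusted over the list alone). Its median and mean lay slightly below 0 while the direction of fry was upward (adjusted p = 0.9148).

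In other lists fewer genes changed with pomalidomide. Of 19 genes of the ATF4 and amino acid response 4 fell, PSAT1 by 0.49 ± 0.08, PHGDH by 0.37 ± 0.06, SHMT2 by 0.24 ± 0.06 and TRIB3 by 0.24 ± 0.06, and 1 rose, or 9 and 1 adjusted over the list alone (fry adjusted p = 0.0217, adjusted p = 0.3496 with an estimated correlation). The list of endoplasmic reticulum chaperones and unfolded protein response genes had a median of -0.07 with 0 of 11 passing, 1 adjusted over the list alone (fry adjusted p = 0.0226, adjusted p = 0.3496 with an estimated correlation; SEL1L -0.22 ± 0.07). Its median was -0.21 beside filanesib plus dexamethasone and -0.06 beside filanesib. The list was not lower with pomalidomide alone (0.01) or beside dexamethasone (0.03). Genes of cholesterol and fatty acid synthesis that fell were INSIG1 by 0.42 ± 0.08, the cholesterol enzyme DHCR7 by 0.35 ± 0.07 and fatty acid synthase, FASN, by 0.31 ± 0.09, 3 of 21, or 4 adjusted over the list alone (fry adjusted p = 0.0532). Where filanesib was absent the arrays of INSIG1 overlapped. They lay at 8.92 to 9.35 with pomalidomide alone against 9.19 to 9.67 in control. Beside dexamethasone they lay at 8.89 to 8.97 against 8.77 to 9.38. Where filanesib was present they did not overlap. Of 18 hypoxia and glycolysis genes 2 fell (3 adjusted over the list alone), ANKRD37 by 0.46 ± 0.08 and lactate dehydrogenase, LDHA, by 0.29 ± 0.07. The pro-apoptotic BMF rose by 0.40 ± 0.07 (adjusted p = 0.0014), whereas BCL2L11 changed by 0.23 ± 0.11 (adjusted p = 0.2618), with 0.53 beside filanesib and 0.57 beside filanesib plus dexamethasone against -0.15 alone and -0.04 beside dexamethasone. Among NF-kappaB response genes 3 of 16 rose, CXCL10, the adhesion molecule ICAM1 (0.45 ± 0.12) and TNF (0.24 ± 0.07), without the list passing (fry adjusted p = 0.0532). Among glucocorticoid response genes 3 of 22 rose (5 adjusted over the list alone), TIPARP by 0.25 ± 0.06, RHOB by 0.29 ± 0.07 and BCL6 by 0.31 ± 0.08, although not beside dexamethasone (0.005) (fry adjusted p = 0.0533). The immediate early genes KLF6 and IER2 rose by 0.26 ± 0.05 and 0.40 ± 0.09, KLF6 not with pomalidomide alone (0.003), and TRIM22, an antiviral gene in the p53 list, by 0.35 ± 0.07. Nucleolar and polyamine genes SRM and MRTO4 fell by 0.24 ± 0.06 and 0.28 ± 0.08, SRM not beside filanesib (-0.004). The average effect of pomalidomide comprised 723 genes, 329 higher and 394 lower. Array weights gave 1210 and a test of every probe set 1103, while 75 changed by at least 1.5-fold.

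**Figure D2:**
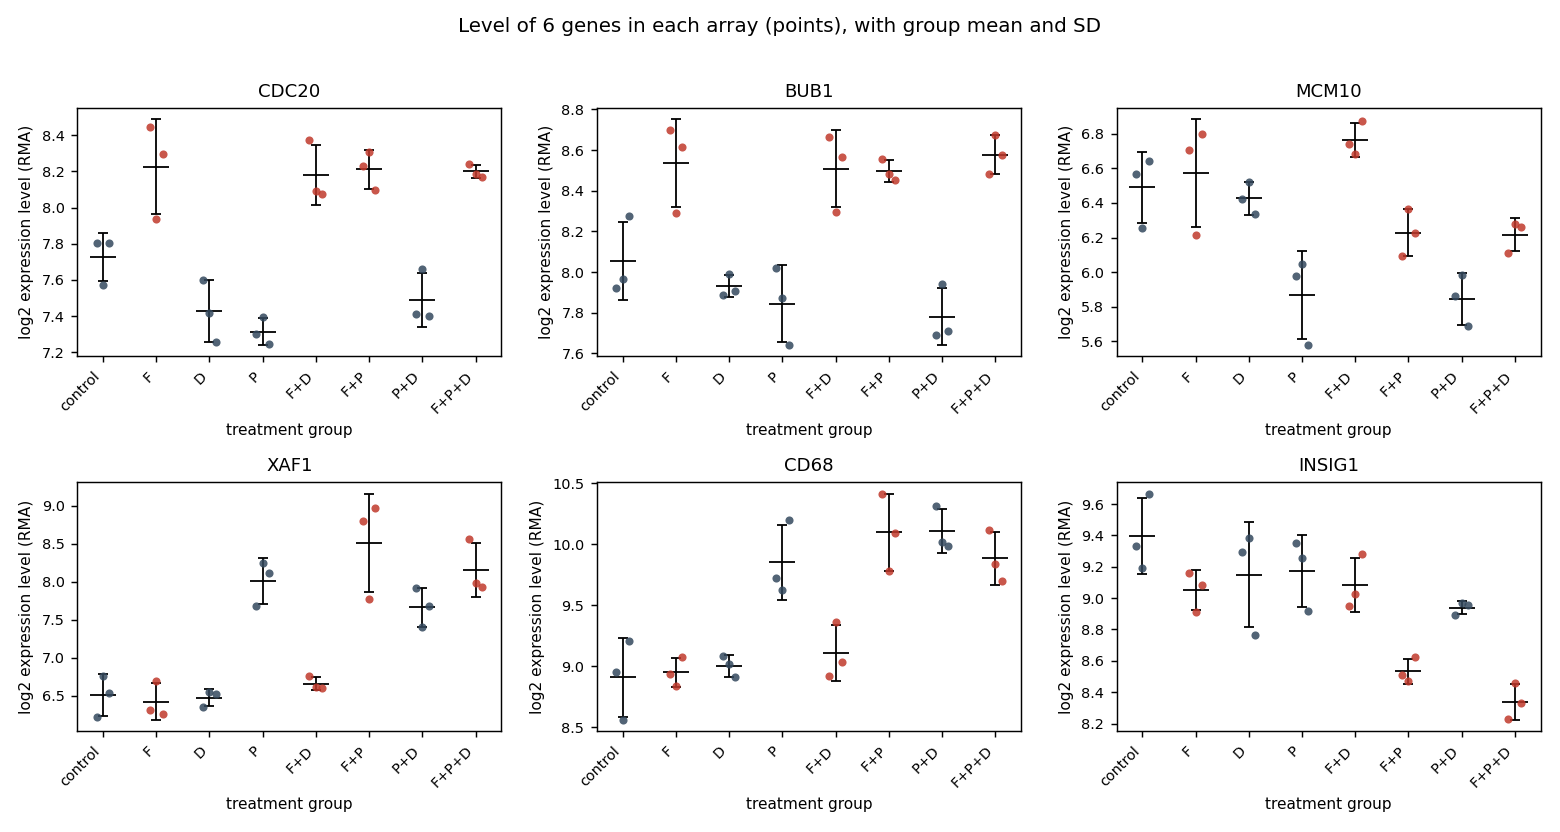
Log2 expression level (RMA) of 6 genes in each array by treatment group (F filanesib, D dexamethasone, P pomalidomide; red points with filanesib, dark points without; horizontal bars are group means and vertical bars SD, 3 arrays per group). CD68 lay at 9.85 ± 0.31 in pomalidomide alone against 8.91 ± 0.33 in control, and INSIG1 at 8.34 ± 0.11 in the triple combination against 9.40 ± 0.24 in control.

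Dexamethasone changed few transcripts. Averaged over backgrounds, limma called 2 genes, the secreted chaperone clusterin, CLU, which fell by 0.55 ± 0.09 (adjusted p = 0.0357), and the microRNA gene MIR876, by 0.35 ± 0.06 (adjusted p = 0.0408). Classical targets of the glucocorticoid receptor did not pass: FKBP5 changed by 0.16 ± 0.08 (adjusted p = 0.6627), TXNIP by 0.17 ± 0.08, DDIT4 by 0.28 ± 0.15 and the insulin receptor substrate IRS2 by 0.31 ± 0.12. The value of DDIT4 came largely from tumours with filanesib plus pomalidomide (0.75), and it was -0.016 beside pomalidomide. FKBP5 was at 0.38 beside filanesib plus pomalidomide and not higher with dexamethasone alone. Of 22 measured glucocorticoid response genes 16 had a positive value and 0 passed, over all genes or adjusted over the list alone, with a median of 0.04 (fry adjusted p = 0.4617). BCL2L11, a known target in lymphoid cells, changed by 0.35 ± 0.11 (adjusted p = 0.4574), and was the 1 of 13 pro-apoptotic BCL2 family genes that rose adjusted over the list alone. The list of endoplasmic reticulum chaperones and unfolded protein response genes was lower with dexamethasone, with a median of -0.06 and 0 of 11 passing over all genes, 3 adjusted over the list alone (fry adjusted p = 0.0082, adjusted p = 0.0932 with an estimated correlation). Values there were -0.27 ± 0.06 for SDF2L1, -0.20 ± 0.06 for MANF, -0.18 ± 0.05 for CALR and -0.15 ± 0.06 for HYOU1, which was not lower beside pomalidomide (0.009). Interferon genes had a median of -0.17, of which 0 of 30 passed over all genes and 2 adjusted over the list alone (fry adjusted p = 0.2806), with CXCL10 at -0.82 ± 0.23, IFITM1 at -0.52 ± 0.17 and IFIH1 at -0.24 ± 0.07. The matrix protein FN1 was at -0.40 ± 0.10 and PECAM1 at -0.34 ± 0.09. Neither passed over all genes, whereas 1 of 8 fibroblast and matrix markers and 2 of 10 endothelial markers were lower adjusted over their list alone. Since human probes register mouse cells only by cross-hybridisation, these values do not show a change in such cells. At an unadjusted p under 0.05 there were 1143 of 14884 genes, where chance gives a share of 0.05. The call of CLU was lost in 13 of 24 omissions of an array, with a replicate block (adjusted p = 0.057) and without pomalidomide replicates 1 and 3 (adjusted p = 0.091), and a test of every probe set called 0 genes. CLU was not in the test of protein-coding genes, because its probe set carried a non-coding accession, and that test called 0 genes too.

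In the triple combination against control, XAF1 rose by 1.65 ± 0.23 (3 arrays against 3, limma adjusted p = 0.0018) and IFI44 by 1.68 ± 0.25 (adjusted p = 0.0024). The innate receptors TLR4 (0.77 ± 0.11) and its homologue CD180 (1.13 ± 0.22) rose, as did the guanine exchange factor DOCK4 (1.30 ± 0.20), CD68 (0.98 ± 0.18), CD200R1 (0.84 ± 0.17), SLFN5 (1.02 ± 0.22), the motor KIFC3 (0.73 ± 0.15) and the microRNA gene MIR4441 (1.58 ± 0.30). INSIG1 fell by 1.06 ± 0.15 (adjusted p = 0.0018), SCD by 0.98 ± 0.19, DHCR7 by 0.87 ± 0.15, the dermatan sulfotransferase CHST14 by 0.88 ± 0.15, AMPD1 by 1.43 ± 0.30, CBLN2 by 1.01 ± 0.19 and CLU by 0.98 ± 0.18. Of 21 cholesterol and fatty acid genes 3 fell over all genes and 8 adjusted over the list alone, with a median of -0.32 (fry adjusted p = 0.0131, adjusted p = 0.1044 with an estimated correlation). The desaturase FADS1 was at -0.73 ± 0.17 (adjusted p = 0.0648). Of 30 interferon genes 2 rose over all genes and 7 adjusted over the list alone (fry adjusted p = 0.0355, adjusted p = 0.1051 with an estimated correlation).

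Endoplasmic reticulum chaperones and unfolded protein response genes were lower as a list in the triple combination than in control, with a median of -0.20 and 0 of 11 passing over all genes, 3 adjusted over the list alone (fry adjusted p = 6.55e-04, and 0.0481 with an estimated correlation). CALR was at -0.40 ± 0.10, HYOU1 at -0.42 ± 0.12 and SDF2L1 at -0.41 ± 0.13. Glycolysis and hypoxia genes were lower as a list, with 0 of 18 passing, 1 adjusted over the list alone, and the glycolytic enzyme TPI1 at -0.44 ± 0.13 (fry adjusted p = 0.0284, adjusted p = 0.1301 with an estimated correlation). The fall was not particular to the triple combination, since the list's mean lay below control in every treated group. It was -0.14 in the triple combination and -0.10 with filanesib alone, dexamethasone alone and the pair of them. No drug's average effect on this list passed (fry adjusted p = 0.0988 for filanesib, 0.8529 for dexamethasone and 0.5348 for pomalidomide). Mitotic genes did not pass against control: 10 of 32 were higher adjusted over the list alone (fry adjusted p = 0.1001), with topoisomerase TOP2A at 0.67 ± 0.16, NEK2 at 0.70 ± 0.19, CCNB1 at 0.62 ± 0.21, BUB1 at 0.52 ± 0.13 and CDC20 at 0.47 ± 0.13. Replication genes did not pass either, with 4 of 27 lower adjusted over the list alone (fry adjusted p = 0.1268), nor did the ATF4 list, with 1 of 19 lower (fry adjusted p = 0.0528; PHGDH -0.47 ± 0.12). BCL2L11 was at 0.62 ± 0.21 (adjusted p = 0.2455), BMF at 0.54 ± 0.14 (adjusted p = 0.1062), IRF4 at -0.63 ± 0.23 and MYC at -0.30 ± 0.13, none passing over all genes. Of 13 pro-apoptotic BCL2 family genes 2 were higher adjusted over the list alone. The triple combination changed 38 genes, 11 up and 27 down. That count was 12 without control replicate 1, 8 without control replicate 3, 13 without replicate 1 of the triple combination, 23 without its replicate 3, 72 without dexamethasone replicate 3, 89 without pomalidomide replicate 3, 64 in a fit to the compared groups only, 91 without pomalidomide replicates 1 and 3 and 350 with array weights. The fit to the compared groups alone ended the calls of the cholesterol and fatty acid, interferon, and chaperone and unfolded protein response lists (adjusted p = 0.0629, 0.1064 and 0.0629). The interferon call was lost without control replicates 1 or 3 or replicate 1 of the triple combination (adjusted p = 0.1006, 0.0823 and 0.1604), and the cholesterol and fatty acid call without control replicate 3 (adjusted p = 0.0738).

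Pomalidomide alone against control combined both movements seen in its average effect. XAF1 rose by 1.5 ± 0.23 (adjusted p = 0.0045), IFI44 by 1.49 ± 0.25 and CXCL10 by 2.00 ± 0.45. Of 30 interferon genes 9 rose over all genes and 18 adjusted over the list alone, with a median of 0.52 (fry adjusted p = 0.0090, adjusted p = 0.0715 with an estimated correlation). The G1/S transcription factors E2F1 and MYBL2 fell by 1.04 ± 0.22 and 1.01 ± 0.17, MYB by 1.07 ± 0.22, GINS2 by 0.91 ± 0.18, the licensing factor CDT1 by 0.81 ± 0.15, the helicase subunit MCM2 by 0.73 ± 0.13 and UHRF1 by 0.64 ± 0.11. Of 27 replication genes 15 fell over all genes and 24 adjusted over the list alone, with a median of -0.64 (fry adjusted p = 6.67e-04, adjusted p = 0.0715 with an estimated correlation). CRBN rose by 0.60 ± 0.11 (adjusted p = 0.0105), MYC fell by 0.51 ± 0.13 (adjusted p = 0.0404) and IRF4 was at -0.74 ± 0.23 (adjusted p = 0.0933). CCNF fell by 0.81 ± 0.17, the passenger complex member CDCA8 by 0.71 ± 0.16, the ribosome assembly factor BOP1 by 0.64 ± 0.12, PHGDH by 0.58 ± 0.12, FASN by 0.66 ± 0.17, ANKRD37 by 0.73 ± 0.17 and LDHA by 0.60 ± 0.14. The ATF4 list, with 1 of 19 fallen and 4 adjusted over the list alone (fry adjusted p = 0.0369), and the hypoxia list (fry adjusted p = 0.0467) were lower, both with adjusted p = 0.4076 with an estimated correlation. The mean of the hypoxia list was -0.13 here and -0.10 with filanesib or dexamethasone alone, so its fall was not particular to pomalidomide. Small Cajal body RNAs, guides for modification of spliceosomal RNA, were among the largest rises: SCARNA6 by 2.44 ± 0.40, SCARNA1 by 2.08 ± 0.46, SCARNA10 by 1.90 ± 0.23 and SCARNA5 by 1.88 ± 0.43.

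Pomalidomide alone changed 294 genes, 75 up and 219 down, and a further quantile normalisation gave 97 up and 101 down. The groups did not overlap in 15.6% of genes, where chance gives 10%. The count depended on single arrays: 23 genes without control replicate 1, 35 without control replicate 3, 828 without pomalidomide replicate 2 and 122 without pomalidomide replicate 3. Array weights gave 62 genes, a fit to these 2 groups only 3, and removal of pomalidomide replicates 1 and 3 left 2. The interferon call was lost without pomalidomide replicate 3 (adjusted p = 0.0829), and both list calls in the fit to these groups only (adjusted p = 0.1663 and 0.1782).

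Filanesib alone against control changed 0 genes in limma, with 587 at an unadjusted p under 0.05. Chance gives a share of 0.05 of the 14884 genes tested, which is more than 587. CCNB1 was at 0.61 ± 0.21, the second mitotic cyclin CCNB2 at 0.59 ± 0.18, MAD2L1 at 0.51 ± 0.14, CDC20 at 0.50 ± 0.13, BUB1 at 0.48 ± 0.13 and KIF11 at 0.25 ± 0.20. Of 32 mitotic genes 31 had a positive value, 7 passed adjusted over the list alone and the median was 0.31 (fry adjusted p = 0.3031). Without filanesib replicate 2, whose mitotic level was near that of control, the list passed (fry adjusted p = 0.0108). That omission takes out the array that went against the rise, so the pass was largely fixed in advance and adds no support. Dexamethasone alone changed 1 gene, SCARNA10, which rose by 1.44 ± 0.23 (adjusted p = 0.0234), with 581 at an unadjusted p under 0.05, also fewer than chance gives. BCL2L11 was at 0.33 ± 0.21 and FKBP5 at -0.02 ± 0.17, a value that turned positive after a further quantile normalisation and in 3 of 6 omissions of an array. The call of SCARNA10 was lost in that setting (adjusted p = 0.0702) and in 5 of 6 omissions of an array of its groups, and omission of an array of another group gave up to 3 genes. Filanesib plus dexamethasone changed 0 genes in limma, with 897 at an unadjusted p under 0.05, 32 with array weights and 7 without dexamethasone replicate 3. There the mitosis list had a median of 0.34 with 5 genes higher adjusted over the list alone and did not pass (fry adjusted p = 0.3712).

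Filanesib plus pomalidomide raised interferon genes: XAF1 by 2.01 ± 0.23 (adjusted p = 1.85e-04), IFI44L by 1.97 ± 0.36, MX2 by 1.58 ± 0.30, and also CD68 by 1.19 ± 0.18, while INSIG1 fell by 0.86 ± 0.15 (adjusted p = 0.0118). Of 30 interferon genes 6 rose over all genes and 23 adjusted over the list alone, with a median of 0.63 (fry adjusted p = 0.0029, and 0.0104 with an estimated correlation). This pair changed 21 genes, 13 up and 8 down. The count was 10 and 9 without control replicates 1 and 3, 4, 57 and 3 without replicates 1, 2 and 3 of the pair, and 149 with array weights. It was 35 and 45 without replicates 1 and 3 of pomalidomide alone, 53 without both, and 33 without replicate 1 of pomalidomide plus dexamethasone. Pomalidomide plus dexamethasone raised CD180 by 1.22 ± 0.22, CD68 by 1.20 ± 0.18 (adjusted p = 0.0057), XAF1 by 1.16 ± 0.23, DOCK4 by 1.04 ± 0.20 and the cobalamin transporter TCN2 by 0.99 ± 0.16. The death-associated kinase DAPK1 fell by 0.99 ± 0.16, the cell cycle phosphatase CDC25A by 0.98 ± 0.16 and MYBL2 by 0.83 ± 0.17. Of 27 replication genes 0 passed over all genes and 18 fell adjusted over the list alone, with a median of -0.41 (fry adjusted p = 0.0229, adjusted p = 0.0854 with an estimated correlation). In 5 of 6 omissions of an array that call was lost. Interferon genes did not pass in this pair, with 1 of 30 higher, 2 adjusted over the list alone (fry adjusted p = 0.2844). It changed 24 genes, 14 up and 10 down. Without control replicates 1, 2 and 3 the count was 8, 11 and 3, without replicates 1 and 3 of the pair 3 and 4, and with array weights 138. Without replicate 3 of pomalidomide alone it was 50, and without its replicates 1 and 3 it was 56.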

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

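Tests chosen only after the result was seen were both differences between pomalidomide effects, the correlation with microRNA probe sets, the removal of pomalidomide replicates 1 and 3, the comparisons of single drugs with control and with combinations, and the comparison of gene counts between treatments within 1 setting. Direct tests of a difference between 2 effects passed for 10 values, 9 of them of small Cajal body RNAs. Filanesib beside pomalidomide and dexamethasone differed from filanesib alone in SCARNA12, by -1.72 ± 0.27 on the log2 scale (SE, limma adjusted p = 0.0264). Pomalidomide beside dexamethasone differed from pomalidomide alone by -4.12 ± 0.65 in SCARNA1 (adjusted p = 0.0123), -3.15 ± 0.57 in SCARNA6, -2.54 ± 0.47 in SCARNA3 and -2.13 ± 0.32 in SCARNA10 (adjusted p = 0.0115), and by 1.07 ± 0.20 in the zinc finger gene ZSCAN16 (adjusted p = 0.0445). Pomalidomide beside filanesib differed from pomalidomide alone by -3.62 ± 0.61 in SCARNA5, -3.37 ± 0.57 in SCARNA6, -2.25 ± 0.32 in SCARNA10 (adjusted p = 0.0050) and -1.62 ± 0.27 in SCARNA12. All 3 sets of calls depended on single arrays. The difference of filanesib effects had 0 genes after a further quantile normalisation, with a replicate block and in a fit to the compared groups only. It also had 0 without control replicate 1 or 3, without filanesib replicate 2 or 3, and without replicate 1 or 2 of pomalidomide plus dexamethasone. Without pomalidomide replicate 2 the differences of pomalidomide effects comprised 19 genes beside dexamethasone and 152 beside filanesib. Over 100 splits of the arrays, 9 gave at least the 1 gene found for filanesib, with 21 the highest among the others, so the splits did not exclude chance there. For pomalidomide beside dexamethasone 4 splits gave at least the 5 genes found (highest other 56), and for pomalidomide beside filanesib 2 gave at least the 4 found (highest other 38). These 2 differences were chosen after the values had been seen, so their splits do not decide whether chance produced them. Splits with 21, 56 and 38 genes gave several times the real counts. All these splits exchanged arrays among all 4 groups, so drug effects entered them and their counts do not show what chance alone gives. Whether anything beyond the drugs raised them was not tested.

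The mean level of the 16 Cajal body RNAs above the median gene level was 7.86 ± 0.32 in control (SD, 3 arrays), 8.53 ± 0.24 in single-drug tumours (9 arrays) and 8.11 ± 0.21 in combinations (12 arrays). Of 23 measured, 4 were higher in single-drug tumours than in control and 6 higher than in combinations. A candidate explanation is that recovery of small structured RNAs differed between samples. Within groups these RNAs deviated together with a mean pairwise correlation of 0.264, between the bounds of 0.1 and 0.3 set in advance, and above the highest of 1000 random gene sets (0.240). Their deviations and those of microRNA probe sets correlated with r = 0.258 (24 arrays, permutation p = 0.2991; rho = 0.264, permutation p = 0.2884; r = 0.387 without the 2 farthest arrays). The microRNA probe sets had array means of 3.43 to 3.51, below the array medians, so they could show a shift only weakly. All 23 small nucleolar and Cajal body RNA genes tested were Cajal body RNAs, so other small nucleolar RNAs could not be compared. Neither a shift of small RNAs nor an effect of treatment was excluded, and the tests did not separate them.

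Pomalidomide alone changed 294 genes, more than any other treatment against control in the fit to all groups. That fit uses 1 spread per gene for all groups, while the arrays of pomalidomide alone differed most from each other. In fits to the compared groups only, pomalidomide alone changed 3 genes and did not lead. The triple combination then changed 64, pomalidomide plus dexamethasone 30 and filanesib plus pomalidomide 27. In the fit to all groups, pomalidomide alone changed 122 genes without its replicate 3, and 62 with array weights. Both counts stayed above the bound set in advance, 1.5 times the next largest count (38), but that bound was wrong, since the same settings raised another treatment to 89 and to 350 genes. With array weights pomalidomide alone no longer led. The weights are estimated from the same spread between arrays, so that loss was largely fixed in advance and leaves unequal quality of the arrays open. The mean change of interferon genes was 0.71 before and 0.65 with weights, and that of replication genes -0.63 and -0.52. Without replicate 3 the 122 genes lay within 1.5 times 89 and left a single aberrant array open. A stronger effect of pomalidomide alone than beside dexamethasone may also contribute: the mean change of replication genes differed by 0.35 (95% interval 0.02 to 0.68, fry p = 0.0438 unadjusted, 0.2021 over all lists, 0.0968 with an estimated correlation).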

How the results depend on the processing

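Tests chosen only after the result was seen were those on protein-coding genes only, those without pomalidomide replicates 1 and 3, omissions of arrays outside the compared groups, and all tests of the 2 differences between pomalidomide effects. The rises of mitotic genes with filanesib and of interferon genes with pomalidomide, and the fall of replication genes with pomalidomide, passed in the average effects under every alternative run for lists and in every omission of an array. Without 1 array their adjusted p ranged from 3.39e-07 to 4.57e-05, from 2.27e-07 to 4.74e-05 and from 4.24e-06 to 5.38e-05. The mitosis list also passed in the triple combination against pomalidomide plus dexamethasone, with adjusted p from 0.0013 to 0.0443. That comparison is part of the filanesib average. Of 226 named values, 207 kept their direction and side of the threshold after quantile normalisation, 220 after median centring, 214 with a trended and robust prior, 208 with a replicate block, 186 with array weights and 170 without pomalidomide replicates 1 and 3. In the fit to the compared groups only, 64 of 104 did. The cause of the changes below was not tested, except that fewer arrays or genes were tested where the setting says so, and a minimum change of 1.5-fold can only lower a count.

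Counts below are of genes past the threshold. After quantile normalisation, dexamethasone alone had 0, the average effect of dexamethasone 1, the difference of filanesib effects 0 and the difference of pomalidomide effects beside dexamethasone 2, and FKBP5 with dexamethasone alone turned to 0.015. Median centring gave 0 for the triple combination against the pair and 2 for the difference beside dexamethasone, with median shifts of all genes of at most 0.083. Without dim genes, those comparisons of the triple with the pair and of the dexamethasone average gave 8 and 1. Array weights gave 1 gene for filanesib, 4 for dexamethasone, 62 for pomalidomide, 32 for filanesib plus dexamethasone, 149 for filanesib plus pomalidomide, 138 for pomalidomide plus dexamethasone, 350 for the triple combination and 82 for the triple against the pair. They gave 330, 6 and 1210 for the average effects of filanesib, dexamethasone and pomalidomide, 2 for the difference of filanesib effects and 3 for the difference beside dexamethasone, and CCNB1 in the pomalidomide average turned to -0.028. With a trended and robust prior, filanesib plus dexamethasone had 2, the difference beside dexamethasone 1 and that beside filanesib 2. A replicate block gave 0 for the triple against the pair, the dexamethasone average and the difference of filanesib effects, and 2 for the difference beside dexamethasone. Replicate numbers do not pair the arrays: after removal of group means, same-number pairs correlated at -0.03 on average and other pairs at 0.01. Of 84 same-number pairs, 25 correlated above 0.1. For 2 of 24 arrays the mean correlation with arrays of other groups was highest for their own number.

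A minimum of 1.5-fold left 180 genes for pomalidomide, and 20, 0 and 75 for the averages of filanesib, dexamethasone and pomalidomide. Testing every probe set gave 27 for dexamethasone, 10 for filanesib plus dexamethasone, 51 for filanesib plus pomalidomide, 15 for pomalidomide plus dexamethasone, 58 for the triple combination, 2 for the triple against the pair, 128, 0 and 1103 for the averages, 9 for the difference beside dexamethasone and 2 for that beside filanesib. In the fit to the compared groups only, pomalidomide had 3 genes, filanesib plus dexamethasone 5, the triple combination 64, the difference of filanesib effects 0 and the differences of pomalidomide effects 1 and 2. Mean list changes were then 0.71 for interferon genes and -0.63 for replication genes with pomalidomide (adjusted p = 0.1663 and 0.1782), and -0.38 for cholesterol and fatty acid genes, 0.55 for interferon genes and -0.22 for chaperones and unfolded protein response genes with the triple combination (adjusted p = 0.0629, 0.1064 and 0.0629). Camera with an estimated correlation left the same means of 0.71 and -0.63 at adjusted p = 0.0715, and those of -0.38 and 0.55 at 0.1044 and 0.1051. Protein-coding genes alone gave 0 for dexamethasone, its average and all 3 differences of effects, and 7 for the triple against the pair.

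Without pomalidomide replicates 1 and 3 there were 4 genes for dexamethasone, 2 for pomalidomide, 53 for filanesib plus pomalidomide, 56 for pomalidomide plus dexamethasone, 91 for the triple combination, 17 for the triple against the pair, 0 for the dexamethasone average, and 1 and 0 for the differences of pomalidomide effects. The remaining array of pomalidomide alone is assumed there to vary like the other groups. Its interferon list was then at 0.64 and its replication list at -0.44 (adjusted p = 0.2106 and 0.1404), CCNB1 in the pomalidomide average turned to -0.088, and BCL2L11 in the filanesib average to -0.002.

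Without 1 array of the compared groups at a time, counts ranged from 0 to 3 for filanesib, 0 to 1 for dexamethasone, 23 to 828 for pomalidomide, 3 to 57 for filanesib plus pomalidomide, 3 to 25 for pomalidomide plus dexamethasone, 8 to 48 for the triple combination, 0 to 2 for the triple against the pair, 130 to 318 for the filanesib average, 0 to 2 for the dexamethasone average, 0 to 1 for the difference of filanesib effects, and 0 to 19 and 1 to 152 for the differences of pomalidomide effects. The highest of these last came without pomalidomide replicate 2, and the 3 genes of filanesib without filanesib replicate 1. Omission of an array of another group, whose spread the fit also uses, gave 0 for filanesib, 1 to 3 for dexamethasone, 208 to 286 for pomalidomide, 0 to 7 for filanesib plus dexamethasone, 16 to 45 for filanesib plus pomalidomide, 18 to 50 for pomalidomide plus dexamethasone, 33 to 89 for the triple combination and 0 to 17 for the triple against the pair. Mean list changes ranged from 0.23 to 0.49 for mitosis with filanesib, 0.55 to 0.84 for interferon with pomalidomide, and -0.44 to -0.33 for cholesterol and fatty acid and 0.39 to 0.67 for interferon genes with the triple combination. Changes of sign occurred for FKBP5 with dexamethasone (-0.17 to 0.084), for IKZF3 (-0.064 to 0.054) and CCNB1 (-0.033 to 0.081) in the pomalidomide average, and for MCL1 (-0.076 to 0.028), IRF4 (-0.36 to 0.022) and MYC (-0.14 to 0.024) in the triple against the pair.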

Other observations

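Tests chosen only after the result was seen were the naming of the genes in the next 2 paragraphs and the test of macrophage markers, and the interval in the lysosome test and the minimum numbers of markers and genes were also added then. Genes that rose in the average effect of pomalidomide were picked by eye and form no tested list. The adaptor STING1 rose by 1.14 ± 0.15 on the log2 scale (SE, 12 arrays against 12, limma adjusted p = 7.81e-05), the RNA helicase RIGI, a member of the interferon list, by 0.87 ± 0.13, TLR3 by 0.48 ± 0.10, TLR4 by 0.40 ± 0.06 and CD180 by 0.76 ± 0.11. The surface peptidase MME, also known as CD10, rose by 1.05 ± 0.21, progranulin, GRN, by 0.88 ± 0.11, TCN2 by 0.87 ± 0.08 and DOCK4 by 0.98 ± 0.10. Falls included the cell cycle genes MYBL2 (by 0.64 ± 0.08), CCNE1 (by 0.60 ± 0.12) and E2F1 (by 0.53 ± 0.11), the complement receptor CR2 (by 0.56 ± 0.09) and the B cell receptor kinase SYK (by 0.36 ± 0.07).

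In the average effect of filanesib the abscission protein CEP55 rose by 0.63 ± 0.08, NEK2 by 0.65 ± 0.10, CCNB2 by 0.59 ± 0.09, TOP2A by 0.52 ± 0.08, MAD2L1 by 0.49 ± 0.07 and the checkpoint kinase TTK by 0.48 ± 0.08. Each drug's effect was also compared across genes between backgrounds that share no arrays, over 7442 genes above the median level. Correlations lay between 0.26 and 0.50 for pomalidomide, between -0.16 and 0.49 for filanesib and between -0.03 and 0.20 for dexamethasone. Genes are not independent replicates, so no p is given.

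CD68 rose with pomalidomide by 0.99 ± 0.09. More macrophages in the tumour may account for it: the other macrophage markers above the median gene level, LAPTM5 (0.01 ± 0.05) and CTSS (0.11 ± 0.07), had a median change of 0.058, but these are only 2, LAPTM5 was near the top of the range at 12.9, and human probes register mouse cells only by cross-hybridisation, so the question stays open. A rise shared by most lysosomal genes was argued against by a list of 54 such genes, of which 26 were measured, with a median of 0.02 and a mean of 0.03 (95% interval -0.04 to 0.09, fry p = 0.4751, n = 12 arrays with and 12 without the drug). CTSB (0.31), CD63 (0.31) and CTSO (0.28) did rise in that list, 3 of 26, where 329 of all 14884 genes rose. A rise of a part of the lysosomal genes thus stays open.

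The hypothesis that the rise of interferon genes extends to antigen presentation was tested on the 6 of 29 such genes that were measured, with a median of 0.06 and fry p = 0.1759 (n = 12 arrays with and 12 without the drug). Their mean of 0.03 (95% interval -0.03 to 0.09) argues against a rise in these 6 as large as the median of 0.53 in interferon genes. B2M rose adjusted over the list alone (0.15 ± 0.05), so a smaller rise stays open, as does any change in the genes not measured. The p met the bound set in advance against the hypothesis, but that bound was wrong because a missed threshold does not show that genes stayed level. The hypothesis that the rise of mitotic genes extends to tubulins could not be tested, because 0 of 21 tubulin genes were named by the probe table.

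Other splits of the same arrays were used to ask how often chance gives as many genes. For average effects, 1 of 100 splits (the real one) reached the 208 genes of filanesib and 1 of 100 the 723 of pomalidomide, with 1 gene the highest of the other splits in each, and 3 of 100 reached the 2 genes of dexamethasone, with 5 the highest. Chance is excluded at 5 in 100 for filanesib and pomalidomide. For dexamethasone the share met that bound, but another split gave more genes than the real one, and 100 splits measure such a share only roughly. The result there rests on 2 genes, and 0 were called in 13 of 24 omissions of an array and under 5 alternatives. Chance thus stays open for dexamethasone. A comparison of 3 arrays with 3 has 10 splits, too few for a share under 5 in 100. Among those, the real split had 294 genes for pomalidomide (highest other 0), 21 for filanesib plus pomalidomide (highest other 0), 24 for pomalidomide plus dexamethasone (highest other 1), 38 for the triple combination (highest other 0) and 1 for the triple against the pair (highest other 0), and in each of these 1 of 10 splits reached it. For dexamethasone 2 of 10 reached its 1 gene (highest other 9), and for filanesib (highest other 0) and filanesib plus dexamethasone (highest other 1) all 10 reached the real count of 0.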
